A study of Homo sapiens with 4 samples.

How the data were processed

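Gene expression was measured on Illumina bead arrays in 4 stable derivatives of HEK293, a human embryonic kidney cell line. The NC line expressed yellow fluorescent protein (YFP) and served as control. AIRE1 and AIRE2 were 2 clonal lines expressing the autoimmune regulator AIRE from a cytomegalovirus promoter, and AIRE-D312A expressed AIRE carrying a mutation in its first PHD finger. Per the labels, each line was studied in 3 independent experiments, which gave 12 arrays, 3 per line. Each line is a single stable line, so p-values measure the spread between experiments with that line, and the effect of a transgene cannot be told apart from other differences between the control line, the clones and the mutant line.

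Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase and purified on columns, and cRNA was amplified and biotin-labelled from 250 ng of total RNA with the TotalPrep kit and stained with streptavidin-Cy3. BeadStudio 3.1.3.0 is named in the submitters' processing notes. The deposited array files hold, per the file headers, the average intensity of each probe on a linear scale and its detection p-value. The values were neither background-subtracted nor normalised between arrays: the median intensity of each array lay close to the mean of the negative controls inferred from the detection p-values (deposited for each array). A further value table by the authors gives 1 intensity per probe and line. Set against the array files, each of its columns equalled a rescaled mean of the replicate 1 and replicate 3 arrays, with no weight on replicate 2. From that mean a background of 56.43 to 57.92 was subtracted. The rest was multiplied by a factor of 1.179 for NC, 0.815 for AIRE1, 0.882 for AIRE2 and 0.825 for AIRE-D312A. Its column medians were 4.02, 3.89, 4.12 and 3.73. How these factors were chosen is not given in the sources used here. That table was used only as an alternative.

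The mean intensity per array lay between 245.6 and 324.3, and 15823 to 17288 of 48701 probes were detected at p under 0.01. The number of arrays, 3 per line, limits the precision. The detection p column of the AIRE-D312A replicate 3 array was 100% equal to that of the AIRE1 replicate 3 array, although its header names another array position on the same slide. It was not used. The negative-control mean and SD and the detection limit of this array were predicted from its 40th percentile of intensity. On the other 11 arrays this prediction, made with each array left out in turn, gave the same detection call for 98.86 to 99.93% of probes, with an error of at most 0.76% in the negative-control mean. The slides of the other arrays are not given in the sources used here, so slide was not fitted as a block.

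The deposited intensities were corrected by normexp with the inferred negative-control parameters and an offset of 16, quantile-normalised over the 12 arrays and log2-transformed (limma 3.58.1 in R 4.3.3). Probes were named through a table of the platform's annotation. It gave 1 gene symbol for 24782 probes, several symbols for 0 probes and no symbol for 23919 probes. Gene IDs matched the RefSeq gene table of GRCh38.p14 for 24154 named probes, whose symbols were updated; that table was used only for names and for the order of genes along chromosomes. Probes detected at p under 0.01 on all 3 arrays of at least 1 line were kept, 16263 in all, of which 2563 had no symbol. Each gene was represented by its brightest probe; 1406 genes had further probes past the filter. This left 11947 of 19304 named genes.

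All 12 arrays entered 1 limma fit with a mean per line, and the 6 pairwise contrasts were tested by moderated statistics with default settings and Benjamini-Hochberg adjustment within each contrast. A gene was called at an adjusted p under 0.05. Genes called the same way in both clones against NC, and in both clones against both NC and AIRE-D312A, were counted as intersections. Where a gene was not detected on any array of the dimmer line, its fold is given as a lower bound: the mean of the brighter line against the mean, over the arrays of the dimmer line, of the higher of the detection limit and the gene's own value, all on the normalised log2 scale. The replicate numbers pair the arrays. Deviations from the line means correlated at 0.332 to 0.61 between arrays of replicate 1, at 0.744 to 0.848 for replicate 2 and at 0.591 to 0.752 for replicate 3, over 6 pairs each, against -0.743 to 0.529 for the 36 pairs of different numbers. For 12 of 12 arrays the best match carried the same number. The fit above has no replicate term; a fit with the replicate number as a block is given beside the counts of each contrast and of list members that it moves by over 1.5 times, and beside the list calls that it changes.

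Gene lists were tested with camera (preset inter-gene correlation 0.01) and adjusted over lists within a contrast. Measured members are those past the detection filter, and a list with fewer than 3 of them was not tested. The 38 lists were APECED autoantigens, thymic tissue-restricted antigens, epidermal differentiation, S100 proteins, simple epithelial genes, mesenchymal and matrix genes, neuronal genes, kidney developmental genes, muscle genes, liver genes, pancreas genes, cancer-testis and germ line genes, haematopoietic genes, endothelial genes, chemokines and cytokines, interferon-stimulated genes, antigen presentation, AIRE partner proteins, H3K4 and H3K27 modifiers, HOX genes, core histones, cell cycle G2 and M, DNA replication, p53 targets, apoptosis regulators, unfolded protein response, amino acid response, heat shock proteins, cholesterol synthesis, hypoxia and glycolysis, metallothioneins, oxidative phosphorylation, cytosolic ribosomal proteins, WNT signalling, TGF-beta and BMP signalling, MAPK feedback genes, ion channels and housekeeping genes. Where counts of called members are given, they are over all genes tested and adjusted over the list alone.

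The lists, the comparisons of lines, their tests and the rule for named genes were fixed before the data were examined. Named genes were AIRE; the 12 genes higher and the 12 lower in both clones against NC with the largest smaller fold change and no overlap between arrays; the 8 highest and 8 lowest called genes of AIRE-D312A against NC without overlap; the 8 genes each way with the largest smallest difference of both clones from both NC and AIRE-D312A; the 6 highest and 6 lowest called genes of AIRE2 against AIRE1; and up to 4 called members of each list with the largest absolute fold change. Genes without an approved symbol were skipped in the ranked parts.

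Alternatives covered background correction, normalisation, the detection filter, the choice of probe, the settings of the empirical Bayes step, array weights, the lines in the fit, the thresholds, the replicate block and leaving out each array in turn. Added after seeing the data were a fit on the arrays of replicates 1 and 3, normexp without detection p-values, AIRE-D312A detection from its arrays 1 and 2, and the count of neighbouring genes outside windows in which all 3 AIRE lines stood apart from NC. For that, the smallest in size of the 3 median differences from NC in a window was set against the largest such value in each of 1000 shuffled gene orders. The lists were also tested again without the 1800 genes of any such window or of any window past the same kind of test between the clones. Chosen after the results were seen as well were the medians by chromosome and window and the tests of the authors' scale factors, of the NC signal and of the AIRE transcript level. The calling step was tested on simulated data for AIRE1 against NC over 11947 genes: it recovered 49.3% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 7 false among 157 calls. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.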

Results

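Genome-wide expression was profiled in HEK293 cells, a human embryonic kidney line, that stably expressed a YFP control (NC), wild-type AIRE in the clones AIRE1 and AIRE2, or the AIRE-D312A mutant. AIRE is a nuclear protein of medullary thymic epithelial cells, where it is known for switching on genes otherwise restricted to other tissues. Each of the 4 lines was represented by 3 arrays from independent experiments. Detected probes per array numbered 15968 ± 127 in NC, 17067 ± 317 in AIRE1, 16382 ± 478 in AIRE2 and 16348 ± 436 in AIRE-D312A (mean ± SD, n = 3 each). In a principal component analysis, the first component (39.3% of the variance) largely separated the replicate 2 arrays from the others, and the second (26.7%) separated NC from the AIRE lines.

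The transcript of AIRE itself was examined first. Its probe was not detected on any of the 3 NC arrays (log2 intensity 4.44 ± 0.10, SD). It was detected on all arrays of the other lines, at 8.90 ± 0.21 in AIRE1, 8.51 ± 0.40 in AIRE2 and 8.31 ± 0.11 in AIRE-D312A (n = 3 each). AIRE was at least 15.6-fold higher in AIRE1, 11.9-fold in AIRE2 and 10.4-fold in AIRE-D312A than in NC, with limma adjusted p = 1.6e-07, 7e-07 and 6.1e-07. Between AIRE lines the largest difference was 0.59 ± 0.18 log2 (SE) in AIRE1 over AIRE-D312A, which was not called (adjusted p = 0.14) but was called with the replicate block (adjusted p = 0.0214). A second AIRE probe was not detected on any array.

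**Figure D1:**
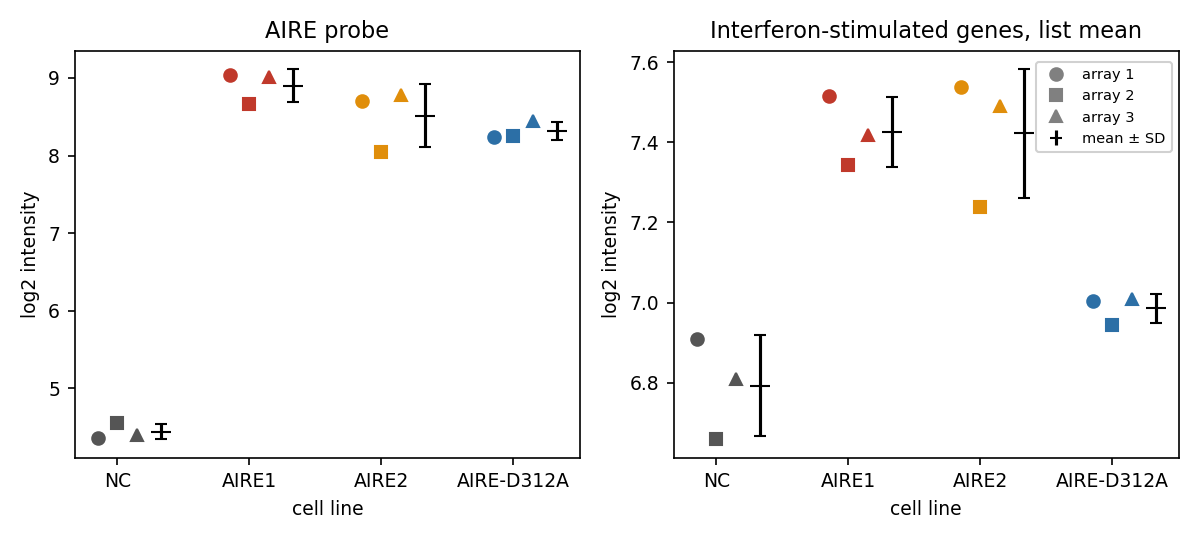
Normalised log2 intensity of the AIRE probe (left) and mean log2 intensity of the 21 measured interferon-stimulated genes (right) on each of the 3 arrays per line, with mean and SD as bars. AIRE lay between 8.05 and 9.03 on the AIRE-expressing arrays and at 4.55 or less in NC, while the interferon list mean lay at 7.24 or more in both clones and at 7.01 or less in AIRE-D312A and NC.

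The first question was which genes both AIRE clones changed against the YFP control. Lipoprotein lipase LPL, which hydrolyses circulating triglycerides, was higher by 2.97 ± 0.40 log2 in AIRE1 and 3.01 ± 0.40 in AIRE2 (SE, n = 3). The membrane protein MAL2 was higher by 2.61 ± 0.15 and 2.68 ± 0.15, the lipocalin LCN15 by 2.60 ± 0.19 and 2.98 ± 0.19. The small heat shock protein HSPB8 rose by 2.44 ± 0.40 and 3.14 ± 0.40, and the matrix protein thrombospondin 2 (THBS2) by 2.40 ± 0.22 and 2.72 ± 0.22. The aldo-keto reductase AKR1C3 rose by 2.37 ± 0.20 and 2.44 ± 0.20, and the transketolase-like gene TKTL1 by 2.37 ± 0.39 and 2.46 ± 0.39. Adjusted p-values of these genes lay between 1.8e-06 (MAL2 in AIRE1) and 0.0026 (HSPB8 and TKTL1 in AIRE1). Further genes were not detected in NC, so that their increase is a lower bound. TMEM47 was at least 4.21-fold higher in AIRE1 and 4.43-fold in AIRE2, the tight junction gene CLDN1 4.72-fold and 3.77-fold. The surface antigen gene LY6G6D was at least 4.52-fold and 3.35-fold higher, and IFIH1, the sensor of viral double-stranded RNA, 3.87-fold and 4.15-fold. Probes of AKR1C3, HBG1, HBG2, ACOT1, ACOT2, SPANXC, SLC2A3, MT1F and the histone genes may also read near-identical relatives, so these genes are uncertain.

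Among genes lower in both clones, the neurofilament gene NEFM stood lowest, at -3.67 ± 0.15 log2 in AIRE1 (adjusted p = 1.6e-07) and -3.14 ± 0.15 in AIRE2 (adjusted p = 7e-07). The calcium channel regulator CRACR2B was at -1.78 ± 0.22 and -1.90 ± 0.22, the matricellular gene CCN3 at -2.0 ± 0.25 and -1.51 ± 0.25, and the ERK phosphatase DUSP4 at -1.48 ± 0.15 and -1.65 ± 0.15. POMZP3 fell by 1.69 and 1.46 on the log2 scale. The homeobox gene UNCX, detected in NC alone, was at least 2.03-fold and 1.93-fold lower. SOX8 stood at -1.24 and -1.41 log2, MSX2 at -1.74 and -1.18, HAND1 at -1.41 and -1.18, and PRDM8 at -1.20 and -1.14. The kinase gene MATK was at least 2.44-fold lower in AIRE1 and at -1.15 log2 in AIRE2, and the leucine zipper gene LZTS1 was at -1.25 and -1.13.

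**Figure D2:**
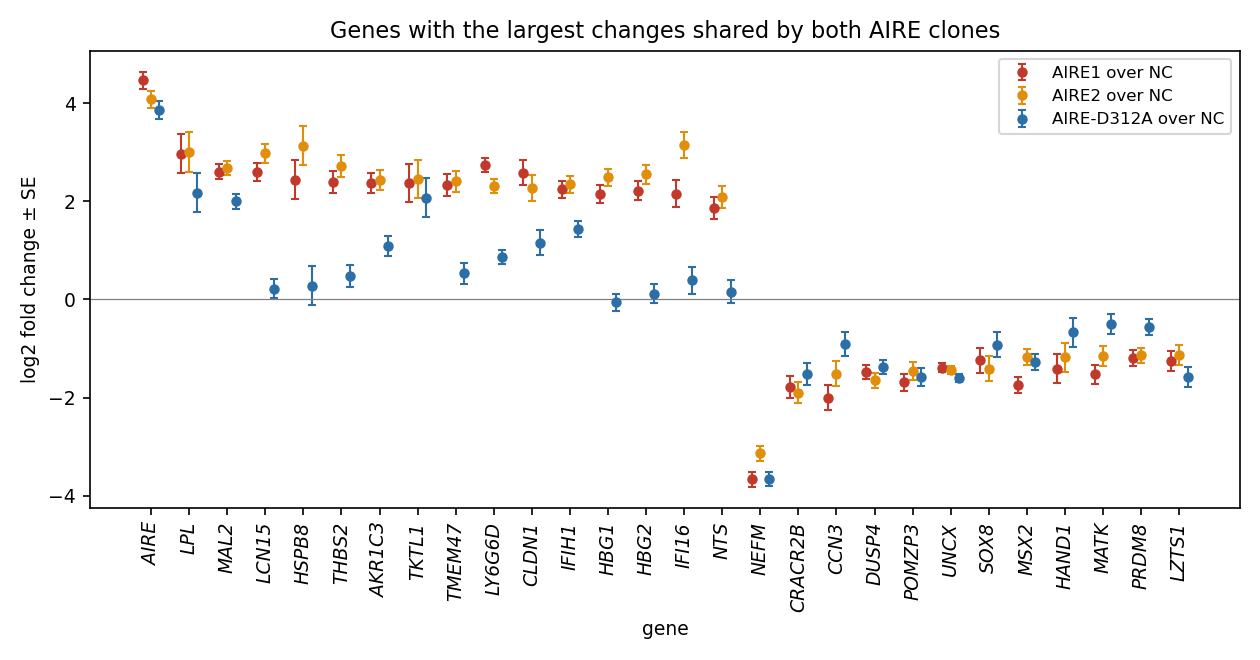
Log2 fold change over NC, with SE, of genes with the largest changes shared by both AIRE clones, for AIRE1, AIRE2 and AIRE-D312A (3 arrays per line). NEFM lay at -3.67, -3.14 and -3.66 in the 3 lines, while LCN15 lay at 2.60 and 2.98 in the clones and at 0.22 in AIRE-D312A.

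In total, limma called 622 genes higher and 366 lower in AIRE1 than in NC, and 709 higher and 421 lower in AIRE2, of 11947 tested. Both clones shared 437 higher and 142 lower genes, and 115 and 15 of these moved 2-fold or more in both. With the replicate block the counts were 1507 and 1215 for AIRE1, 1692 and 1491 for AIRE2, and 1053 and 582 for the shared genes, and every gene called without the block was also called with it. With median centring in place of quantile normalisation, which moved the median of all genes by 0.13 log2 in AIRE1, the splits were 652 higher and 107 lower in AIRE1, 516 and 72 in AIRE2, and 393 and 36 in both. Single arrays moved several counts: the higher count of AIRE1 was 396 without its replicate 1. The lower count of AIRE1 was 230 and 205 without NC replicates 1 and 3 and 197 and 200 without AIRE1 replicates 1 and 2. That of AIRE2 was 267 and 261 without NC replicates 1 and 3 and 258 and 250 without AIRE2 replicates 1 and 3. The shared lower count was 89 and 81 without NC replicates 1 and 3 and 85 and 92 without AIRE1 replicates 1 and 2.

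Immune gene groups were examined next, since AIRE acts in antigen-presenting thymic cells. Of 21 measured interferon-stimulated genes, 11 were higher and 10 not called in AIRE1, and 11 were higher, 2 lower and 8 not called in AIRE2. The antiviral enzyme gene OAS3 was at least 3.75-fold and 4.34-fold higher, the antiviral GTPase gene MX1 was higher by 1.25 and 1.46 log2, and IFITM3, which blocks viral entry, was higher by 0.49 in AIRE1 and lower by -0.42 in AIRE2. The list median was 0.57 in AIRE1 (camera adjusted p = 4.3e-09, adjusted p = 0.03 with an estimated correlation) and 0.62 in AIRE2 (adjusted p = 1.4e-06, adjusted p = 0.072 with an estimated correlation). Adjusted over the list alone, 12 genes were higher and 1 lower in AIRE1, and 14 higher and 3 lower in AIRE2. Of 19 antigen presentation genes, 5 were higher in AIRE1 and 7 in AIRE2, with 14 and 12 not called. Adjusted over the list alone these were 10 and 9. Among them the peptidase gene ERAP2 was higher by 1.15 and 1.23 log2, the class II gene HLA-DRA at least 2.05-fold in AIRE1, and HLA-DRB1 and HLA-DMA by 1.20 and 1.17 log2 in AIRE2. The median of this list was 0.56 and 0.52 (camera adjusted p = 3.2e-06 and 2.9e-06, adjusted p = 0.16 and 0.13 with an estimated correlation). Fitting the replicate block, limma called 13 interferon-stimulated genes higher and 3 lower in AIRE1, and 14 and 3 in AIRE2, and 13 antigen presentation genes higher in AIRE1 and 14 higher and 1 lower in AIRE2.

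Genes of tissues other than kidney were covered by several lists. Few of their members named on the array were measured: 5 of 37 cancer-testis, 6 of 22 haematopoietic and 6 of 33 thymic genes. HBG1, HBG2, SPANXC, SPP1 and S100A8 were detected on the 6 arrays of the clones alone and so passed the filter through them. CD8A, detected on 5 arrays, also passed it through the clones alone. The share of measured genes that rose is therefore partly set by the filter. Of 5 measured cancer-testis and germ line genes, 4 rose in each clone, and as many when adjusted over the list alone. They were TKTL1, the germ cell bridge gene TEX14 by 0.89 and 0.90 log2, SPANXC at least 1.27-fold and 1.17-fold, and PRAME by 0.38 and 0.37 log2. The list median was 0.77 and 0.65 (camera adjusted p = 0.00061 and 0.00034, adjusted p = 0.03 and 0.042 with an estimated correlation), and without the detection filter the list was not called (adjusted p = 0.59 and 0.43). Of 6 haematopoietic genes, 3 rose in each clone, and 3 over the list alone. They were the fetal globin genes HBG1 (at least 3.25-fold and 4.1-fold) and HBG2 (at least 3.21-fold and 4.02-fold) and the T cell coreceptor gene CD8A (at least 1.17-fold in AIRE2, and on 2 of 3 arrays in AIRE1). Their median was 0.22 in AIRE1 (camera adjusted p = 0.015, adjusted p = 0.21 with an estimated correlation), with 0.06 with the replicate block and 0.46 without the detection filter. It was 0.46 in AIRE2 (adjusted p = 0.00034, adjusted p = 0.078 with an estimated correlation). Of 6 thymic tissue-restricted antigens, 3 rose in AIRE1 and 2 in AIRE2, or 4 and 2 over the list alone. The bone and milk protein gene SPP1 was at least 1.49-fold and 1.17-fold higher, the neutrophil protein gene S100A8 at least 1.12-fold and 1.56-fold, and the myelin gene MBP 0.99 log2 higher in AIRE1. The list median was 0.47 and 0.34 (camera adjusted p = 0.00087 and 0.0085, adjusted p = 0.03 and 0.078 with an estimated correlation).

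Epithelial and mesenchymal lists were compared next. Of 11 simple epithelial genes, 3 rose in AIRE1 and 5 in AIRE2, with 7 and 5 over the list alone. The adhesion molecule EPCAM was higher by 1.02 and 2.76 log2, the protease inhibitor SPINT2 by 1.37 and 1.76, the tight junction gene CLDN3 at least 1.55-fold and 1.85-fold, and the keratin KRT8 by 0.95 log2 in AIRE2. The medians were 0.48 and 0.24 (camera adjusted p = 0.0071 and 0.0068, adjusted p = 0.056 and 0.072 with an estimated correlation), and without the detection filter the list was not called (0.15 and 0.088). Of 7 S100 genes, 2 rose in AIRE1 and 3 in AIRE2, or 3 and 4 over the list alone, with S100A4 at 0.57 and 0.62 log2. The list was called in AIRE2 (median 0.47, camera adjusted p = 0.024; 0.053 with the replicate block, adjusted p = 0.32 with an estimated correlation) and not in AIRE1 (median 0.17, adjusted p = 0.15). In the mesenchymal and matrix list of 23 genes, 1 rose and 4 fell in AIRE1, including vimentin (VIM, -1.39) and the repressor genes ZEB2 (-1.02) and SNAI2 (-0.95), and 1 rose and 1, SNAI2 (-1.31), fell in AIRE2. Over the list alone 3 were higher and 4 lower in AIRE1, and 3 and 2 in AIRE2. The list itself was not called (medians 0.00 and 0.09, adjusted p = 0.58 and 0.9). Of 16 neuronal genes, 2 rose and 2 fell in each clone, while over the list alone 2 were higher and 3 lower in AIRE1, and 6 and 3 in AIRE2. INA was higher by 0.83 and 1.25 log2 and GAP43 by 0.98 and 0.60, and NEFL was lower by -0.73 in AIRE1. The list was not called (medians 0.15 and 0.30, adjusted p = 0.56 and 0.21), its mean in AIRE1 being -0.04. The replicate block gave 5 neuronal genes higher and 3 lower in AIRE1, and 8 and 3 in AIRE2, and 6 mesenchymal genes higher and 5 lower in AIRE1, and 5 and 5 in AIRE2. Among simple epithelial genes the block gave 7 higher and 1 lower, and 5 and 1, and among S100 genes 3 and 1 in AIRE1 and 4 higher in AIRE2.

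The remaining tissue lists were not called in either clone against NC. Of 30 APECED autoantigens named on the array, the targets of autoantibodies in AIRE deficiency, 8 were measured. Among these the decarboxylase gene DDC rose, by 1.35 and 1.11 log2 (list medians 0.05 and 0.07, camera adjusted p = 0.63 and 0.79). The epidermal list of 7 genes had medians of 0.11 and -0.05 (adjusted p = 0.56 and 0.75), with S100A8 called in both clones. Muscle genes, with ACTC1 at least 1.06-fold higher in AIRE2, had adjusted p = 0.29 and 0.053, liver genes 0.82 and 0.27, pancreas genes 0.5 and 0.29, and chemokines and cytokines 0.15 and 0.1. In the last list IL15, a growth factor of lymphocytes, rose by 1.77 and 1.14 log2, IL23A at least 1.05-fold in AIRE1 and CX3CL1 at least 1.15-fold in AIRE2. The endothelial list had 2 measured members and was not tested. Its member VWF, the von Willebrand factor gene, was at least 1.7-fold and 1.27-fold higher. Over the list alone, 2 APECED autoantigens were higher and 1 lower in AIRE1 and 1 higher in AIRE2, and 2 pancreas genes were higher and 1 lower in AIRE1. Higher over the list alone were also 1 epidermal gene in each clone, 1 and 2 muscle genes, 1 liver gene in AIRE2 and 2 chemokines and cytokines in each. The replicate block gave 2 higher and 1 lower, and 1 and 1, for APECED autoantigens, 1 and 1, and 2 and 1, for epidermal genes, and 2 and 1 in AIRE1 and 1 higher in AIRE2 for pancreas genes. With it 2 and 2 muscle genes, 1 and 2 liver genes and 3 and 2 chemokines and cytokines were higher.

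Chromatin and developmental genes included groups moving in both directions. Of 17 core histone genes, 8 rose in AIRE1 and 6 in AIRE2, or 9 and 7 over the list alone. H2AC18 was higher by 1.76 and 1.52 log2, H2AJ by 1.26 and 1.20, H2BC21 by 0.98 and 1.06, and H3C10 by 1.19 in AIRE1. The medians were 0.45 and 0.42 (camera adjusted p = 3.2e-07 and 2.5e-05, adjusted p = 0.03 and 0.042 with an estimated correlation). Of 22 HOX genes, which set positional identity, 2 rose and 7 fell in AIRE1 while 8 fell in AIRE2. Over the list alone 9 and 11 were lower. HOXB8 was at -1.09 and -1.13 log2, HOXC8 at -0.95 and -0.67 and HOXC4 at -0.78 and -0.43, whereas HOXD11 rose by 0.79 in AIRE1. The medians were -0.31 and -0.34 (camera adjusted p = 0.00053 and 0.00013, adjusted p = 0.03 and 0.042 with an estimated correlation). Of 7 kidney developmental genes, 3 fell in AIRE1 (4 over the list alone), with LHX1 at -0.89, SIX2 at -0.45 and EYA1 at -0.49 (median -0.35, camera adjusted p = 0.00053, adjusted p = 0.03 with an estimated correlation). In AIRE2, LHX1 (-0.98) and SIX2 (-0.41) fell and EYA1 rose by 0.51, also over the list alone, and the list was not called (adjusted p = 0.16). The 27 AIRE partner proteins were not called (medians 0.00 and -0.01, adjusted p = 0.96 and 0.68), with XRCC5 0.47 log2 higher in AIRE2. Nor were the 22 H3K4 and H3K27 modifiers (medians -0.02 and 0.03, adjusted p = 0.63 and 0.97), with CBX2 at -0.45 in AIRE2. XRCC5 and CBX2 were also the calls over these lists alone. Under the replicate block, 12 and 11 core histone genes were higher, 2 HOX genes were higher and 11 lower in AIRE1 and 13 lower in AIRE2, and 5 kidney developmental genes were lower in AIRE1. The block gave 2 lower in AIRE1 and 2 higher and 1 lower in AIRE2 for AIRE partner proteins, and 2 lower in AIRE1 and 1 higher and 2 lower in AIRE2 for the modifiers.

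Signalling and metabolic lists followed. Of 23 WNT genes, 3 rose and 4 fell in each clone. Cyclin D1 (CCND1) was at -1.23 and -0.87 log2 and WNT5A at -0.86 and -0.72, and the inhibitors SFRP1 and RNF43 were higher by 1.28 and 1.66, and by 0.90 and 0.71. The list was called in AIRE1 (median -0.21, camera adjusted p = 0.013, adjusted p = 0.47 with an estimated correlation) and not in AIRE2 (adjusted p = 0.1). Adjusted over the list alone, 3 were higher and 9 lower in AIRE1, and 3 higher and 4 lower in AIRE2. Of 15 MAPK feedback genes, 1 rose and 3 fell in each clone. EGR1 rose by 0.78 and 0.95, DUSP4 and MYC (-0.53 and -0.59) fell in both, DUSP5 was at -0.73 in AIRE1 and SPRED1 at -0.72 in AIRE2. The AIRE1 median was -0.24 (adjusted p = 0.0088, adjusted p = 0.34 with an estimated correlation), and AIRE2 was not called (adjusted p = 0.26). Over the list alone, 1 was higher and 3 were lower in each. With the replicate block, 3 WNT genes were higher and 10 lower in AIRE1, and 4 and 8 in AIRE2, and 1 MAPK feedback gene was higher and 7 lower in AIRE1, and 3 and 3 in AIRE2.

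Of 19 TGF-beta and BMP genes, 2 rose and 4 fell in each clone, or 3 and 6 in AIRE1 and 3 and 5 in AIRE2 over the list alone. LEFTY2 was higher by 1.39 and 1.34 and SMAD6 was at -1.06 and -0.98, with ID2 at -1.76 in AIRE1 and FST at least 1.84-fold higher in AIRE2. The list was not called (adjusted p = 0.069 and 0.34), while in AIRE1 it was called with the replicate block (0.025), without the detection filter (0.013) and with median centring (0.0084). The block gave 5 higher and 8 lower in AIRE1, and 4 and 6 in AIRE2. Of 16 cholesterol synthesis genes, HMGCS1 (-0.94) and MVD (-0.32) fell in AIRE1, where 4 were lower over the list alone. Its median was -0.24 in AIRE1 (adjusted p = 0.014, adjusted p = 0.16 with an estimated correlation) and -0.19 in AIRE2 (adjusted p = 0.027, adjusted p = 0.18 with an estimated correlation). With the replicate block 7 genes were lower in AIRE1 and 4 in AIRE2. Of 19 heat shock genes, HSPB8 and HSPA1A (0.59 log2) rose in AIRE1, also over the list alone. The list median there was 0.21 (adjusted p = 0.013, 0.095 with median centring, adjusted p = 0.21 with an estimated correlation). In AIRE2 the list had adjusted p = 0.068, and 0.018 with the replicate block, which gave 7 higher genes in AIRE1 and 4 in AIRE2. Of 3 metallothioneins, MT1F rose by 1.51 and 1.78 log2, and 2 genes rose over the list alone. The medians were 0.96 and 1.04 (adjusted p = 0.048 and 0.024, adjusted p = 0.16 and 0.11 with an estimated correlation). The replicate block gave 2 and 3 higher genes, and without the detection filter this list was not called (0.29 and 0.41). Of 28 DNA replication genes, RFC2 (-0.52) and MCM7 (-0.31) fell in AIRE2, and 3 were lower over the list alone, with CDC45 at -0.60. The medians were 0.00 in AIRE1 (adjusted p = 0.51) and -0.11 in AIRE2 (adjusted p = 0.024, adjusted p = 0.079 with an estimated correlation). RFC2 and MCM7 lay in windows of neighbouring genes on chromosome 7 with medians of -0.38 and -0.30 in AIRE2 over NC, and CDC45 in a window on 22 that was also lower in AIRE2 than in AIRE1. Fitted with the block, 2 replication genes were lower in AIRE1 and 6 in AIRE2. Without 4 genes in such windows the list had adjusted p = 0.041 (adjusted p = 0.093 with an estimated correlation).

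Several lists were not called in either clone. They were p53 targets (adjusted p = 0.43 and 0.78), cell cycle genes (0.23 and 0.1), apoptosis regulators (0.63 and 0.95), the amino acid response (0.63 and 0.67) and hypoxia and glycolysis (0.27 and 0.78). The others were oxidative phosphorylation (0.47 and 0.67), cytosolic ribosomal proteins (0.97 and 0.67), ion channels (0.32 and 0.75), housekeeping genes (0.97 and 0.9) and the unfolded protein response (0.32 and 0.078, with 0.03 in AIRE2 with the replicate block). Some of their members were called. In AIRE1, TP53I3 was higher by 1.29 log2, KCND2 by 0.61 and KCNH2 at least 1.21-fold, with CACNA1H at -0.82, EGLN3 at -0.77 and SDHA at -0.65. In AIRE2, ENO2 was higher by 1.16 log2, MANF by 0.54, PLK1 by 0.50, DNAJB11 by 0.47, NDUFS1 by 0.41 and PTTG1 by 0.37, with PPIA at -0.52 and TBP at -0.39. In both, the glucose transporter gene SLC2A3 was higher by 1.68 and 1.91, with HRK at -0.96 and -0.42, BCL2 at -0.63 and -0.39 and ADM at -0.61 and -0.43. Over the lists alone, ion channels had 3 higher and 1 lower in AIRE1 and apoptosis regulators 2 higher and 2 lower in AIRE2, and the other lists had as many calls as over all genes. The replicate block gave, in AIRE1 and AIRE2, 5 and 8 higher genes for the unfolded protein response, 3 higher for cell cycle genes in AIRE1 and 8 higher and 3 lower in AIRE2, and 1 higher and 4 lower p53 targets in each. It gave 2 higher and 4 lower, and 3 and 5, for apoptosis regulators, 1 and 2, and 2 and 2, for the amino acid response, and 5 and 4, and 2 and 2, for ion channels. For oxidative phosphorylation it gave 1 higher and 2 lower, and 4 and 1, for hypoxia and glycolysis 2 and 4, and 2 and 1, for housekeeping genes 1 and 2 in AIRE1 and 3 lower in AIRE2, and 1 ribosomal gene higher in AIRE1. With median centring the ribosomal list was called lower in AIRE1 (adjusted p = 0.0028). That setting turned the direction of the ribosomal list in AIRE2, of the amino acid response and housekeeping lists in AIRE1 and of oxidative phosphorylation in both clones. The test's direction differed from the sign of the median or mean for the p53, H3K4, epidermal and housekeeping lists in AIRE2, the neuronal and ribosomal lists in AIRE1 and apoptosis regulators in both clones.

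**Figure D3:**
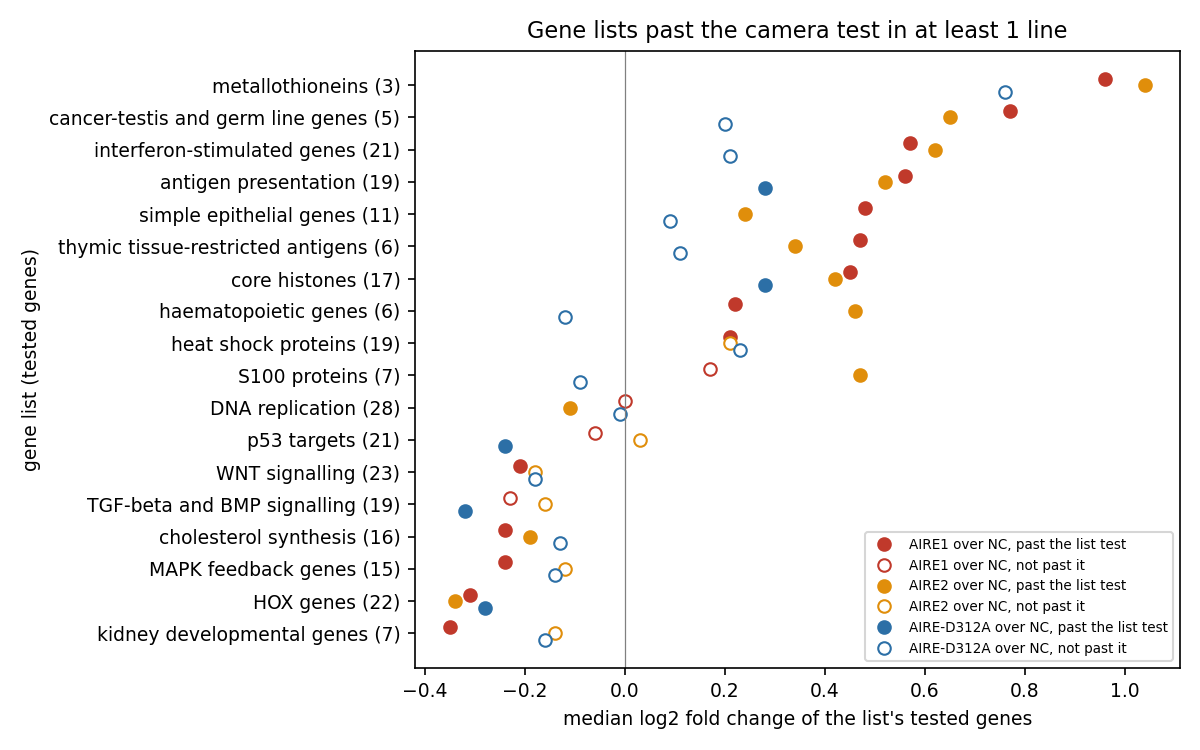
Median log2 fold change over NC of each gene list past the camera test in at least 1 line, with the number of measured genes in brackets. Filled points passed the list test and open points did not (AIRE1, AIRE2 and AIRE-D312A, 3 arrays each). Cancer-testis genes lay at 0.77 and 0.65 in the clones and 0.20 in AIRE-D312A, and HOX genes at -0.31, -0.34 and -0.28.

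The next question was what the PHD finger mutant changed against the control. The growth hormone receptor gene GHR was 2.57 ± 0.16 log2 higher in AIRE-D312A than in NC (adjusted p = 3.9e-06), the acyl-CoA thioesterase gene ACOT1 2.51 ± 0.15 (adjusted p = 3.8e-06). LPL was higher by 2.18 ± 0.40, TKTL1 by 2.08 ± 0.39 and MAL2 by 2.00 ± 0.15, and ACOT2 and TOX3 at least 2.91-fold and 2.49-fold (n = 3). GHR, ACOT1, ACOT2 and TOX3 were also higher in both clones, GHR by 1.71 and 2.49 log2 and ACOT1 by 2.09 and 2.68. NEFM was lower by -3.66 ± 0.15 log2, POMZP3 by -1.58, LZTS1 by -1.58, the calcitonin-related gene CALCB by -1.58 and the inhibitor of differentiation gene ID2 by -1.59, and UNCX was at least 1.93-fold lower. KLHL4 was at least 4.21-fold and the lymphotoxin receptor gene LTBR at least 3.76-fold lower (adjusted p = 1.1e-05 and 5.5e-06). KLHL4 differed from NC by 0.39 in AIRE1 (adjusted p = 0.29) and by -1.94 in AIRE2 (adjusted p = 7.8e-05), and LTBR by -0.79 in AIRE1 (adjusted p = 0.0092) and 0.18 in AIRE2 (adjusted p = 0.59).

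Of the lists, 5 passed the test in AIRE-D312A against NC. Core histones had 3 higher of 17 (5 over the list alone; median 0.28, camera adjusted p = 0.00026, adjusted p = 0.1 with an estimated correlation), with H2AC18 at 0.86 log2. Antigen presentation had 2 higher of 19 (5 over the list alone; median 0.28, adjusted p = 0.0014, adjusted p = 0.4 with an estimated correlation), with ERAP2 at 1.88. HOX genes had 1 lower of 22, HOXB4 at -0.59, and 1 over the list alone (10 with the replicate block; median -0.28, adjusted p = 0.00026, adjusted p = 0.049 with an estimated correlation). TGF-beta and BMP genes had 6 lower of 19, also over the list alone, with SMAD6 at -0.87 (median -0.32, adjusted p = 0.00054, adjusted p = 0.4 with an estimated correlation). The p53 list had a median of -0.24 (adjusted p = 0.047, 0.053 without the detection filter, 0.056 outside windows that differed between the clones or from NC, adjusted p = 0.4 with an estimated correlation), and 5 of its genes were lower with the replicate block. The interferon list had 4 higher and 2 lower of 21, with IFIH1 at least 2.21-fold and OAS3 at least 1.56-fold higher and IFITM3 at -1.0, or 7 higher and 2 lower over the list alone. Its median of 0.21 did not pass the list test (adjusted p = 0.052), while without the detection filter and with median centring it did (0.0035 and 0.049). It also did over the 15 genes outside those windows (median 0.29, adjusted p = 7.5e-05, adjusted p = 0.21 with an estimated correlation). The windows were chosen on the lines' own differences. They held IFITM1, IFITM2, IFITM3 and IRF7, at -0.54, -0.78, -1.0 and -0.49, besides ISG20 (0.21) and SP110 (1.1). That call is therefore no separate support. Cancer-testis genes (adjusted p = 0.24), haematopoietic genes (0.34), thymic antigens (0.57), simple epithelial genes (0.15) and kidney developmental genes (0.09) were not called. Heat shock genes (0.06), metallothioneins (0.09), oxidative phosphorylation (0.053) and the unfolded protein response (0.09) were called with the replicate block (0.0091, 0.028, 0.026 and 0.028). Metallothioneins were also called with median centring (0.049), and oxidative phosphorylation without the detection filter (0.0078). Members higher with the replicate block were 7 of the core histones and 8 of antigen presentation, with 1 lower. It gave 8 higher and 5 lower for the interferon list and 1 higher and 9 lower for TGF-beta and BMP genes.

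Limma called 316 genes higher and 158 lower in AIRE-D312A, of which 78 and 16 by 2-fold or more. The counts were 1041 and 923 with the replicate block and 199 and 30 with median centring. Several arrays moved them. The higher count was 190 without NC replicate 3 and 166, 199 and 202 without AIRE-D312A replicates 1, 2 and 3. The lower count was 75 and 73 without NC replicates 1 and 3 and 54, 70 and 75 without AIRE-D312A replicates 1, 2 and 3.

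The mutant line serves as a control for the PHD finger, so genes were sought that differed in both clones from both NC and AIRE-D312A. There were 60 genes higher in this sense, 18 of them by 2-fold or more. LCN15 was higher than in AIRE-D312A by 2.38 ± 0.19 log2 in AIRE1 and 2.75 ± 0.19 in AIRE2 (adjusted p = 9.4e-05 and 4.8e-05). HSPB8 was higher by 2.16 and 2.86, THBS2 by 1.93 and 2.24, and the neuropeptide gene NTS by 1.71 and 1.93 (1.87 and 2.09 over NC). HBG1 was at least 3.34-fold and 4.22-fold and HBG2 at least 3.3-fold and 4.14-fold higher than in AIRE-D312A. The interferon-inducible DNA sensor gene IFI16 was at least 3.12-fold and 6.17-fold higher than in NC and higher by 1.78 and 2.76 log2 than in AIRE-D312A (adjusted p = 0.0045 and 0.00026), and TMEM47 was higher by 1.81 and 1.88. For LCN15, HSPB8, THBS2, NTS, HBG1, HBG2, IFI16 and TMEM47, AIRE-D312A was not called different from NC (adjusted p from 0.27 to 0.94), although TMEM47 was with the replicate block (adjusted p = 0.02). The 5 genes lower in both clones than in both other lines were the glutamate transporter gene SLC1A3 (-1.10 and -0.72 against AIRE-D312A), C10orf41 (-1.54 and -1.04), the potassium channel gene KCNB2 (-0.58 and -0.48), the complement gene CFD (-0.52 and -0.84) and SIX2 (-0.47 and -0.43).

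The same lists were compared between each clone and AIRE-D312A. Interferon-stimulated genes had 5 higher in AIRE1 and 6 in AIRE2, and 10 and 11 over the list alone. Among them were OAS3 by 1.26 and 1.48 log2, IFITM3 by 1.49 and 0.57 and IFIH1 by 0.81 and 0.91. The medians were 0.45 and 0.33 (camera adjusted p = 9.6e-10 and 5.4e-08, adjusted p = 0.055 and 0.083 with an estimated correlation). Haematopoietic genes had 3 higher in each, and 3 and 4 over the list alone. Their medians were 0.34 and 0.64 (adjusted p = 1.4e-05 and 5.4e-08, adjusted p = 0.063 and 0.066 with an estimated correlation), with 0.074 in AIRE1 without the detection filter. Cancer-testis genes had 3 higher in each, also over the list alone, which added 1 lower in AIRE1. Their medians were 0.59 and 0.58 (adjusted p = 0.0029 and 0.0036, adjusted p = 0.063 and 0.083 with an estimated correlation, 0.77 and 0.45 without the filter). Thymic antigens had 2 and 1 higher, and 4 and 3 over the list alone. Their medians were 0.43 and 0.30 (adjusted p = 0.00021 and 0.0072, adjusted p = 0.055 and 0.089 with an estimated correlation), with 0.074 in AIRE1 without the filter. S100 genes had 1 and 3 higher, and 2 and 3 over the list alone. Their medians were 0.22 and 0.27 (adjusted p = 0.015 and 0.001, adjusted p = 0.49 and 0.22 with an estimated correlation), with 0.3 in AIRE1 without the filter. In the fit with the replicate block 11 interferon-stimulated genes were higher in AIRE1 and 11 higher and 1 lower in AIRE2, 4 and 3 thymic antigens were higher, and 2 and 3 S100 genes.

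Some lists passed the test against AIRE-D312A in 1 clone. In AIRE1 these were core histones, with 2 higher and 3 over the list alone (median 0.18, adjusted p = 0.0013, adjusted p = 0.082 with an estimated correlation). Kidney developmental genes had 1 lower, SIX2, also over the list alone (median -0.20, adjusted p = 0.015, 0.054 with median centring, adjusted p = 0.087 with an estimated correlation). Chemokines had IL15 higher, and 3 over the list alone (median 0.10, adjusted p = 0.015, adjusted p = 0.087 with an estimated correlation). They had 0.05 with the replicate block and 0.074 without the filter. In AIRE2, TGF-beta and BMP genes had FST higher by 0.79 log2, and 4 over the list alone (median 0.25, adjusted p = 0.01, adjusted p = 0.49 with an estimated correlation). Muscle genes had ACTC1 at least 1.1-fold higher, also over the list alone (median 0.32, adjusted p = 0.01, 0.07 without the filter, 0.17 outside windows, where ACTC1 does not lie, adjusted p = 0.22 with an estimated correlation). With the replicate block, antigen presentation was called higher in both clones (adjusted p = 0.13 and 0.065 without it, 0.038 and 0.02 with it), and p53 targets in AIRE2 (0.083 and 0.033). The block gave 5 higher core histone genes and 3 higher chemokines in AIRE1, and 6 higher TGF-beta and BMP genes and 3 higher muscle genes in AIRE2. Single genes of other lists differed too. KRT8 was higher in both clones, by 1.56 and 1.75 log2, and SPARC (1.52), CCNB2 (0.44) and B2M (0.64) were higher in AIRE1. ERAP2 was lower in both, by -0.74 and -0.65, and CYCS (-0.84) was lower in AIRE2.

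By single contrasts, limma called 187 genes higher and 93 lower in AIRE1 than in AIRE-D312A, and 160 higher and 105 lower in AIRE2. With the replicate block these were 708 and 462, and 974 and 896, with 234 genes higher and 64 lower in both clones against both other lines. With median centring they were 137 and 22, and 83 and 13. The higher count of AIRE1 fell to between 70 (without its replicate 1) and 111 (without its replicate 2) when any of the 6 arrays was left out. Its lower count fell to between 38 and 56 (without its replicates 1 and 3). In AIRE2 the higher count was 466 and the lower 260 without its replicate 2, and between 67 and 82, and 19 and 37, without any other array of the pair. The lower count was also 57 and 65 without AIRE1 replicates 1 and 2. The count of 60 was 110 without AIRE2 replicate 2, and 29, 37, 34, 30, 28 and 32 without AIRE1 replicates 1 and 3, AIRE2 replicate 3 and AIRE-D312A replicates 1, 2 and 3. The count of 5 was 1 and 2 without NC replicates 1 and 2, 2, 2 and 3 without AIRE1 replicates 1, 2 and 3, and 2 without AIRE2 replicate 1. It was 1 without each AIRE-D312A replicate and 0 by limma without AIRE2 replicate 3 (59 at an unadjusted p under 0.05 with all arrays).

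How far the 3 AIRE lines resembled each other was measured over all 11947 genes, which are not independent replicates. Log2 fold changes over NC of AIRE1 and AIRE2 correlated at 0.77 (Pearson) and 0.65 (Spearman), those of AIRE1 and AIRE-D312A at 0.71 and 0.67, and those of AIRE2 and AIRE-D312A at 0.67 and 0.57. In 100 simulations of unchanged lines sharing the NC arrays the mean correlation was 0.5 and the highest 0.53. The simulated arrays were drawn independently, without the pairing by replicate number and without any difference particular to the NC line. These simulated values are therefore only a rough guide to what unchanged lines would give. The covariances were 0.0895, 0.0653 and 0.0631 against a simulated 0.0167, which leaves differences of 0.0727, 0.0486 and 0.0464. Independent lists would share 36.9 higher and 12.9 lower genes between the clones, against 437 and 142 observed, and EYA1, IFITM3 and TNFRSF10A were called in opposite directions. AIRE1 and AIRE-D312A shared 224 higher (16.5 for independent lists) and 91 lower (4.84) genes, and AIRE2 and AIRE-D312A 255 (18.8) and 109 (5.57). The highest number of shared calls between the simulated clones was 1. Because NC was 1 line with 3 arrays and could not be divided, part of the excess may come from the shared controls or from that line itself. Of the 437 shared higher genes, 208 were also called higher in AIRE-D312A and 96.3% had the same sign there, with medians of 0.83, 0.82 and 0.51 log2 in AIRE1, AIRE2 and AIRE-D312A. Of the 142 lower genes, 69 were also called and 97.9% had the same sign (medians -0.63, -0.57 and -0.47). Both sets were chosen against the same NC arrays, so some agreement in sign would arise in an unchanged line too. How much was not measured. The share called different from AIRE-D312A in both clones was 13.7% of the higher and 3.52% of the lower genes.

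**Figure D4:**
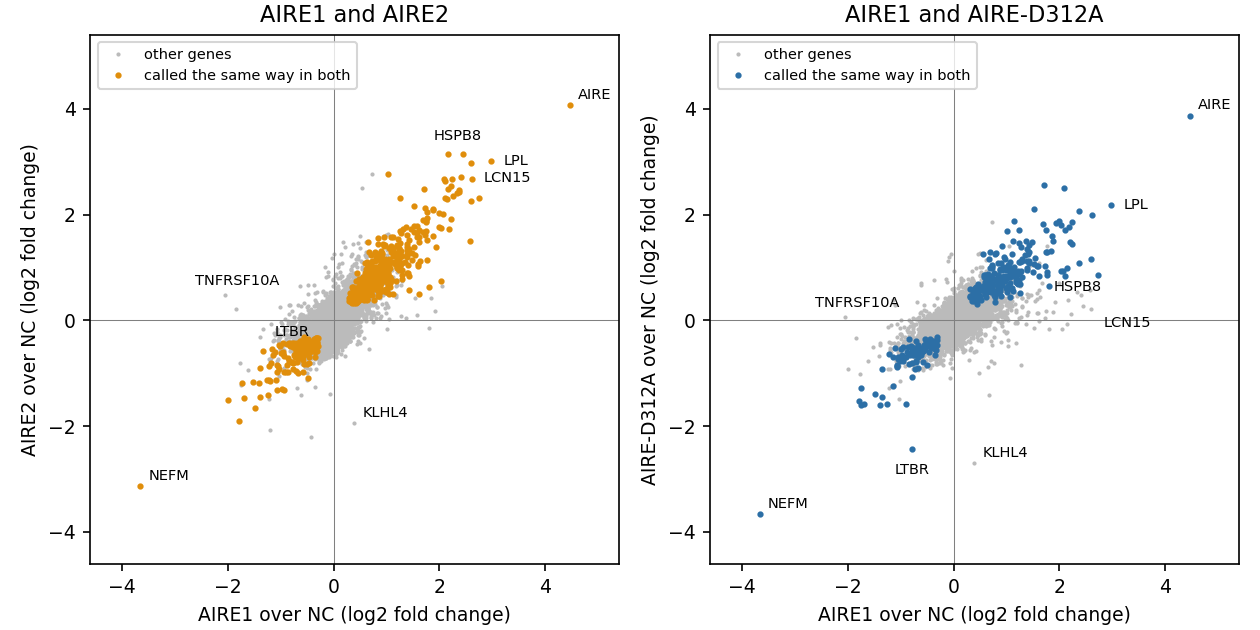
Log2 fold change over NC of each of the 11947 genes in AIRE2 (left) or AIRE-D312A (right) against that in AIRE1. Coloured points are genes called the same way in both lines, 437 higher and 142 lower on the left and 224 higher and 91 lower on the right. LCN15 and HSPB8 lay high in both clones, at 2.60 and 2.44 in AIRE1, and at 0.22 and 0.28 in AIRE-D312A.

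Differences between the 2 clones of the same construct were tested directly. The death receptor gene TNFRSF10A was at least 4.67-fold higher in AIRE2 than in AIRE1 (adjusted p = 1e-06) and its divergent transcript TNFRSF10A-DT 2.07 ± 0.15 log2 higher. Both were lower in AIRE1 than in NC, at least 3.35-fold and by -1.84 log2. The LIM domain gene CSRP1 (2.04 ± 0.25), the hyaluronan receptor gene CD44 (1.97 ± 0.22), EPCAM (1.74 ± 0.21) and the protocadherin PCDH19 (1.32 ± 0.15) were higher in AIRE2. KLHL4 (-2.32 ± 0.19), CPXM1 (-1.95 ± 0.17), the hyaluronan synthase gene HAS2 (-1.77 ± 0.13), FAM162B (-1.47 ± 0.14) and TNFRSF14 (-1.41 ± 0.23) were lower, and ADGRB3 was at least 2.64-fold lower (n = 3). Their limma adjusted p lay between 4.8e-05 for HAS2 and 0.0096 for TNFRSF14. None of the tested lists was called between the clones by camera, the lowest adjusted p being 0.1, for haematopoietic genes and for hypoxia and glycolysis. An unadjusted p under 0.05 was found for 4 lists.

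Limma called 122 genes higher and 153 lower in AIRE2 than in AIRE1, 698 and 897 with the replicate block and 26 and 29 with median centring. Without AIRE1 replicate 1 the counts were 51 and 44, without AIRE1 replicates 2 and 3 they were 62 and 60, and 60 and 56. Without AIRE2 replicates 1 and 3 they were 62 and 58, and 71 and 71, and without AIRE2 replicate 2 the higher count was 251. The lower count was 95, 101 and 100 without AIRE-D312A replicates 1, 2 and 3. The differences followed the order of genes along chromosomes. On chromosome 7 the median difference of 552 genes was -0.30 log2, and -0.31, -0.29 and -0.28 in the 3 pairs of arrays. On chromosome 15 it was -0.26 over 399 genes (-0.28, -0.27 and -0.28), and on chromosome 22 -0.20 over 285 genes (-0.20, -0.16 and -0.22). Against NC these medians were -0.27, -0.24 and -0.18 in AIRE2, 0.03, 0.03 and 0.01 in AIRE1, and 0.02, -0.22 and 0.00 in AIRE-D312A. In windows of 25 neighbouring genes, 58 of 464 had a permutation p under 0.05 against the largest window of each of 1000 shuffled gene orders. They were 21 of 22 on chromosome 7, 13 of 15 on 15, 8 of 11 on 22, and 4, 6, 5 and 1 on chromosomes 5, 6, 9 and X. The windows from CCDC127 to ATPSCKMT and from RAI14 to PLCXD3 on chromosome 5 were higher in AIRE2 by 0.53 log2 each, and there AIRE1 stood at -0.58 and -0.36 against NC. Chromosomes 6, 7, 9, 15 and 22, chosen after these values were seen, held 20.3% of the placed genes and 123 (80.4%) of the 153 genes lower in AIRE2, among them RFC2 and CCNB2. GHR and SDHA lay in windows on chromosome 5 with medians of 0.29 and 0.53, and ADGRB3 in a window on chromosome 6 with a median of -0.23. Of the other genes described, LCN15, POMZP3, UNCX, SLC1A3, DDC, CLDN3, ACTC1, MCM7, CYCS, HMGCS1, FST, SMAD6, SPRED1, KCNH2, KCND2, B2M and PPIA lay in such windows.

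**Figure D5:**
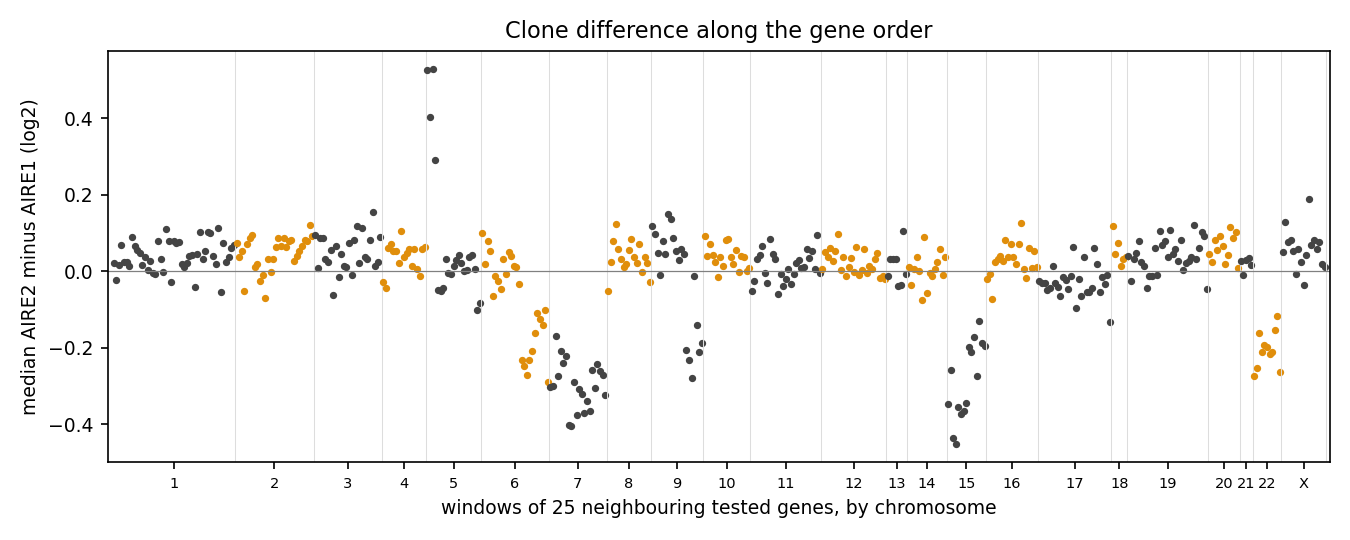
Median log2 difference AIRE2 minus AIRE1 (3 arrays each) of each of 464 windows of 25 neighbouring tested genes, in gene order, with alternating colours for chromosomes. Windows on chromosome 7 lay between -0.41 and -0.17 and those on chromosome 15 between -0.45 and -0.13, and the 2 highest, at 0.53, lay on chromosome 5.

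Because AIRE is known for switching on silent genes, detection itself was compared. A gene was gained if 1 of its probes was detected at p under 0.01 on all 3 arrays of a line. In addition, none of its probes was detected at p under 0.05 on any NC array. Lost genes were counted the other way round. In AIRE1, 118 genes were gained and 3 lost. In AIRE2 these numbers were 71 and 2, and in AIRE-D312A 28 and 2. Both clones gained 49 genes, AIRE itself included, and lost UNCX. Among the gained were the retinal dehydrogenase gene ALDH1A1, the gastrin receptor gene CCKBR, the testis cyclin CCNA1 and the mast cell protease CPA3. Others were the coagulation factor F5, the neuropeptide receptor NPY1R and the cancer-testis genes PAGE4 and CT45-4. Of the 49, 11 were not detected at p under 0.05 in AIRE-D312A either: HBG1, HBG2, IFIT2, KRT27, NMUR2, POMC, PROM1, SERPINA5, SPANXC, TNMD and TSPAN8. These genes were counted without a test, and the examples outside the rule for named genes were chosen after their values were seen. Several genes compared by intensity were detected on part of a line's arrays. In NC, THBS2, HSPB8, LEFTY2, MT1F, IL15, DDC and H3C10 were detected on 2 of 3 arrays and ACOT1, TEX14 and TP53I3 on 1. In AIRE-D312A, SPARC, FST and LEFTY2 were detected on 2 arrays and IFI16 on 1. SIX2 was detected on 1 array of each clone, TNFRSF10A-DT on 1 in AIRE1, and CPXM1 on 1 and MATK and TNFRSF14 on 2 in AIRE2. Without AIRE2 replicate 2, AIRE2 gained 163, both clones 85 and both clones over AIRE-D312A 21. Without AIRE1 replicate 3, AIRE1 lost 5, and AIRE-D312A gained 52 without NC replicate 1. Losses were 4 in AIRE2 without its replicate 2, 2 in both clones without AIRE1 replicate 2, and 4, 5, 7 and 4 in AIRE-D312A without NC replicates 2 and 3 and its own replicates 1 and 3.

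Genes were divided into 4 bins of 2986 or 2987 by mean intensity. Of the 437 shared higher genes, 192 (43.9%) were in the lowest bin, 133 in the next, 74 in the one above and 38 (8.7%) in the highest. The 142 shared lower genes were spread as 29, 33, 53 and 27. The lowest bin thus held 1.76 times its share of higher genes. Without the detection filter, which adds genes not detected in any line, it held 0.01 times its share. The shared higher genes also neighboured each other. Of pairs of adjacent tested genes, 44 were both higher, against a mean of 15.8 and a highest of 32 in 10000 permutations of the calls (one-sided permutation p = 1e-04, the smallest they can give). Pairs included IFIT1, IFIT2 and IFIT3, HBG1 and HBG2, the histone genes H2AC18, H4C15, H2BC21 and H2AC20, TNFRSF11B and MAL2, and IFIH1 and GCA. Without pairs of the same symbol stem there were 32 against a mean of 15.2 (permutation p = 2e-04).

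Some regions differed from NC in all 3 AIRE lines, a comparison chosen after the window medians were seen. In 15 of the 464 windows the 3 medians lay on the same side of NC with a permutation p under 0.05. On chromosome 2, 6 windows from HSPE1 to PER2 were higher, by 0.25 to 0.48 log2, and on X the window from ARMCX3 to PWWP3B, by 0.32 in AIRE1, 0.47 in AIRE2 and 0.29 in AIRE-D312A. On chromosome 5 the window from SHROOM1 to HNRNPA0 was higher by 0.15 to 0.27, and on chromosome 11, 7 windows were lower, at -0.42 to -0.17. The 8 higher windows, of 200 genes, held 46 (10.6%) of the 434 placed shared higher genes, and the 7 lower ones, of 175 genes, 18 (12.8%) of the 141 placed shared lower genes. Of the 44 neighbouring pairs, 14 had a gene in these windows, 9 on chromosome 2 and 5 on X. Outside them there were 30 pairs against a mean of 13 in 10000 permutations (one-sided permutation p = 1e-04, the smallest they can give). Those 30 still held the pairs of the same symbol stem, such as HBG1 and HBG2. Leaving out such pairs and the windows together was not tested, so whether neighbouring goes beyond both is open. Among the genes described above, NDUFS1 and XRCC5 lay in the windows on chromosome 2, and CRACR2B, CALCB, CD44, IFITM3 and ADM in those on chromosome 11. The interferon genes IFITM1, IFITM2 and IRF7 shared the window of IFITM3, and stood at -0.44, -0.33 and 0.15 log2 in AIRE1, -0.91, -0.59 and -0.19 in AIRE2 and -0.54, -0.78 and -0.49 in AIRE-D312A. Without the 1800 genes of these windows and those that differed between the clones, 44 of 46 list calls were also made, the exceptions being p53 targets in AIRE-D312A against NC and muscle genes in AIRE2 against AIRE-D312A. Besides the interferon list in AIRE-D312A, 4 lists were called there and not over all genes. In AIRE2 over NC they were cell cycle genes (median 0.21, adjusted p = 0.008, adjusted p = 0.049 with an estimated correlation), the unfolded protein response (0.20, adjusted p = 0.041, adjusted p = 0.17 with an estimated correlation) and WNT genes (-0.18, adjusted p = 0.049, adjusted p = 0.39 with an estimated correlation). Against AIRE-D312A it was oxidative phosphorylation (-0.05, adjusted p = 0.035, adjusted p = 0.5 with an estimated correlation). The windows were chosen on differences in the same arrays, so leaving out their genes can by itself move a list. The cell cycle genes left out all stood lower in AIRE2 than in NC, at -0.30 to -0.07 log2. Calls gained outside the windows are therefore no separate support for these lists.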

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

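The tests of the authors' scale factors, of a stronger NC signal and of the AIRE transcript level were chosen only after the results were seen, as were the medians by chromosome and window and the list medians outside windows.

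Neighbouring genes differed together between the 2 AIRE clones, with a correlation across genes of 0.29 over 11847 pairs against a highest of 0.036 in 10000 permutations of the gene order. Paralogs with similar symbols are argued against, since the correlation was 0.28 over the 11352 pairs of different symbol stems. Array bias along the gene order is argued against as well, since replicate 2 against replicates 1 and 3 gave 0.022 (one-sided permutation p = 0.0097). Chromosome regions that differ between the clones, for example in copy number, may therefore account for part of the clone differences on chromosomes 7, 15 and 22 and in parts of 5, 6, 9 and X. DNA was not analysed here, so copy number and regional regulation stay open, and the correlation was also above its permutations in the other contrasts, from 0.09 (AIRE1 against NC) to 0.191 (AIRE2 against AIRE-D312A).

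In the authors' value table, genes measured in every line lay lower in the AIRE lines than in NC, with medians of -0.40, -0.29 and -0.37 log2 in AIRE1, AIRE2 and AIRE-D312A over 11968 probes. A stronger NC signal on the arrays is argued against, since before scaling the AIRE lines stood higher than NC, by 0.12, 0.13 and 0.14. The value nearest to that of the table was 0.13. Whether NC held more transcripts could not be tested, because cRNA was made from a fixed amount of total RNA. After each column was divided by its scale factor the medians were 0.13, 0.13 and 0.14, and the share of probes lower than in NC fell from 89.5, 82.3 and 90.1% to 30.7, 30.7 and 27.9%. The largest of these medians, 0.14, lay outside the bound of 0.1 set for the scale factors as the whole cause, but that bound had not allowed for the 0.12 to 0.14 already present on the arrays. The division could not serve as a test, since each column equalled its factor times the background-subtracted mean of replicates 1 and 3. It returns the arrays' own values by construction. The shift of the table below the arrays thus follows from the factors, 1.179 for NC and 0.815 to 0.882 for the AIRE lines. Why these were chosen was not tested.

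Interferon-stimulated genes had list medians of 0.57 and 0.62 log2 over NC in AIRE1 and AIRE2 and 0.21 in AIRE-D312A, with 11 of 21 called higher in AIRE1, and 11 higher and 2 lower in AIRE2. With an estimated correlation the list was still called in AIRE1 (adjusted p = 0.03) and no longer in AIRE2 (adjusted p = 0.072). Outside the windows that differed between the clones or from NC the medians of 15 genes were 0.80, 0.77 and 0.29. There the list was called in both clones with an estimated correlation (adjusted p = 0.025 and 0.033) and not in AIRE-D312A (adjusted p = 0.21). Those windows were chosen on the same differences. They held IFITM1, IFITM2, IFITM3 and IRF7, at -0.91, -0.59, -0.42 and -0.19 in AIRE2, besides ISG20 (1.03) and SP110 (0.99). The call in AIRE2 outside them is therefore no separate support. The arrays of replicate 2 are argued against as the source, since without them the medians were 0.69, 0.66 and 0.17. A difference in AIRE transcript level cannot be told apart from an effect of the mutation, because AIRE in AIRE1 against AIRE-D312A had adjusted p = 0.14, or 0.0214 with the replicate block. AIRE stood at 8.51 in AIRE2 and 8.90 in AIRE1 (adjusted p = 0.37), and on 1 array, AIRE2 replicate 2, AIRE was 8.05 and the list mean 7.24, against 8.24 to 8.44 and at most 7.01 in AIRE-D312A, but 1 array excludes nothing, so the level stays open, as do, untested, the PHD finger mutation and differences between single lines unrelated to AIRE.

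With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, reached the real count in each contrast. Fitted on the 6 arrays alone, limma called 759 genes in AIRE1 against NC, 418 in AIRE2 against NC, 283 in AIRE-D312A against NC, 376 in AIRE1 against AIRE-D312A, 60 in AIRE2 against AIRE-D312A and 48 in AIRE2 against AIRE1. The highest of the other splits gave 0 genes by limma in each, also among those of the 4 splits parting every replicate pair that were not the real one. At an unadjusted p under 0.05 the real splits gave 2282, 1882, 1787, 1846, 1421 and 1320 genes in that order, and the highest others 2151, 2302, 2773, 2285, 3339 and 3011.

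For genes called the same way in both clones against NC, chance could not be excluded over free regroupings of the 9 arrays: 5 of 100 gave as many genes, the real one included, with 417 real and 1088 at the highest other. The other 4 all put the 3 replicate 2 arrays in the place of NC, which points to the structure by replicate number. Regrouped within replicate numbers, 1 of 100 gave as many (highest other 290), and with the replicate block 1 of 100 (1407 real, 853 at the highest other). For genes called in both clones against both NC and AIRE-D312A, 1 of 100 regroupings of the 12 arrays was as large, the real one. It gave 65 genes, against 30 at the highest other, which kept the NC and the AIRE-D312A arrays together and mixed those of the clones. The calls thus followed the division into lines. Regrouping arrays of single lines cannot tell whether the clones differ from the other lines by chance. Within replicate numbers the highest other was 2 genes, and with the block it was 0 by limma against 298.

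Several named genes drew attention because limma called a difference between AIRE2 and AIRE1, clones of the same construct. Differences in log2, AIRE2 minus AIRE1, were 2.54 for TNFRSF10A, 2.07 for TNFRSF10A-DT, 2.04 for CSRP1, 1.97 for CD44, 1.74 for EPCAM and 1.32 for PCDH19. They were 0.98 for LTBR, 0.78 for GHR, 0.74 for ZEB2, 0.69 for SDHA, 0.67 for S100A3, 0.64 for ACOT2, 0.54 for HRK and 1 for EYA1. Lower in AIRE2 were KLHL4 (-2.32), CPXM1 (-1.95), HAS2 (-1.77), ADGRB3 (-1.74), FAM162B (-1.47), TNFRSF14 (-1.41), IFITM3 (-0.91), HOXD11 (-0.75), RFC2 (-0.51), VWF (-0.43), TBP (-0.42) and CCNB2 (-0.38). For TNFRSF10A, S100A3 and ADGRB3, not detected in the dimmer clone, these are fitted values, and the bounds are at least 4.67-fold, 1.5-fold and 2.64-fold. Of 25 of these genes with a window, 5 lay in a window past the permutation test, namely GHR, ADGRB3, CCNB2, RFC2 and SDHA.

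Probes without a gene name, left out of the gene comparisons except where all filtered probes were tested one by one, also carried signal above the control line. Of 2563 such probes tested, limma called 59 higher and 12 lower in both clones than in NC, and 6 of the higher ones also against AIRE-D312A.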

How the results depend on the processing

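The fit on the arrays of replicates 1 and 3, normexp without detection p-values, AIRE-D312A detection from arrays 1 and 2, the neighbour count outside windows apart from NC and the list tests outside windows were chosen only after the data were seen; all other settings were fixed before the data were examined. Counts of called genes are given as higher and lower, and for settings not listed they stayed within 1.5 times the reported count. Stricter thresholds leave fewer calls by construction, and for every other moved count the cause was not tested.

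The replicate block, which matches the pairing of the arrays, gave 1507 and 1215 genes in AIRE1 against NC, 1692 and 1491 in AIRE2 against NC, 1041 and 923 in AIRE-D312A against NC, 708 and 462 in AIRE1 against AIRE-D312A, 974 and 896 in AIRE2 against AIRE-D312A, and 698 and 897 in AIRE2 against AIRE1. In both clones it gave 1053 and 582 against NC, and 234 and 64 against both other lines. It added calls, as these counts show. Every gene called without it was also called with it, and 388 of 388 calls of named genes were also made with it. Of the list calls it ended 3 of 46, and besides the calls reported with it, it changed no other list call. Array weights gave, in the same order, 1567 and 1472, 1878 and 1593, 1213 and 1229, 964 and 699, 1681 and 1466, and 1170 and 1174, with 1051 and 632 in both clones against NC and 282 and 74 against both other lines.

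At an adjusted p under 0.01 the counts were, again in that order, 355 and 156, 396 and 165, 156 and 47, 73 and 39, 63 and 17, and 48 and 36. In both clones they were 251 and 55 against NC, and 26 and 0 against both other lines, where limma gave 59 lower genes at an unadjusted p under 0.05. At 2-fold or more they were 175 and 53, 206 and 25, 78 and 16, 50 and 15, 49 and 5, and 16 and 14, with 115 and 15 in both clones against NC and 18 and 0 by limma against both other lines.

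Median centring gave 107 lower genes in AIRE1 and 72 in AIRE2 against NC, 199 and 30 in AIRE-D312A against NC, 22 lower in AIRE1 and 83 and 13 in AIRE2 against AIRE-D312A, 26 and 29 in AIRE2 against AIRE1, and 36 and 1 lower in both clones against NC and against both other lines. It moved the median of all genes against NC by 0.13 log2 in AIRE1, 0.06 in AIRE2 and 0.06 in AIRE-D312A. With only the 2 lines compared in the fit, there were 322 and 96 genes in AIRE2 and 210 and 73 in AIRE-D312A against NC, 50 and 10 in AIRE2 against AIRE-D312A, and 30 and 18 in AIRE2 against AIRE1. With the arrays of replicates 1 and 3 there were 609 lower genes in AIRE1, 1113 and 637 in AIRE2 and 489 and 433 in AIRE-D312A against NC, 745 and 417 in AIRE2 against AIRE-D312A, 357 and 286 in AIRE2 against AIRE1, and 127 higher in both clones against both other lines. The 5 genes lower in both clones against both other lines became 3 with cyclic loess and 3 with all filtered probes tested one by one.

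At a detection p under 0.05, genes gained and lost numbered 216 and 10 in AIRE1, 148 and 13 in AIRE2, 78 and 10 in AIRE-D312A and 101 and 4 in both clones, and 26 were gained in both clones and not in AIRE-D312A. The lowest intensity bin held 1.76 times its share of shared higher genes and 0.82 times that of lower genes. Without the detection filter these were 0.01 and 0, and the lower value was 0.44 without background correction. These ratios thus depend on the detection filter, that is, on signal over background.

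Leaving out each array in turn gave 396 to 777 higher and 197 to 461 lower genes in AIRE1 against NC, 482 to 1029 and 250 to 564 in AIRE2 against NC, and 166 to 399 and 54 to 236 in AIRE-D312A against NC. Against AIRE-D312A it gave 70 to 257 and 38 to 116 in AIRE1, and 67 to 466 and 19 to 260 in AIRE2, and between the clones 51 to 251 and 44 to 222. Both clones shared 304 to 550 and 81 to 151 against NC, and 28 to 110 and 0 to 6 by limma against both other lines. The highest count of called genes in each of these comparisons came without AIRE2 replicate 2. Genes gained and lost numbered 118 to 161 and 3 to 5 in AIRE1, 71 to 163 and 2 to 4 in AIRE2, 28 to 52 and 2 to 7 in AIRE-D312A, and 49 to 85 and 1 to 2 in both clones, with 11 to 21 in both clones and not in AIRE-D312A.

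For 135 named genes, 388 calls were recomputed to 10392 alternative values. Of these, 9305 held. Among them were 138 in the authors' value table, which allows no test, judged by direction and size alone, and the rest stayed called in the same direction. A further 921 were no longer called, 165 moved in the authors' value table and 1 reversed. This was PTTG1 in AIRE-D312A against NC, at -0.001 log2 in the authors' value table. Of 46 list calls, 10 held with an estimated correlation, 44 with median centring, 31 without the detection filter, 43 with the replicate block and 44 outside the windows. The fry test, which asks whether a list moves one way and not whether it differs from other genes, also called 41 of these lists. Testing all probes one by one was not run for single genes, and a slide block was not run because the slides of the arrays are not given in the sources used here.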
